A study of Homo sapiens with 24 samples.

How the data were processed

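Tumours grown from LAPC-4, an established human prostate cancer cell line, were profiled on Affymetrix human expression arrays. Per the series' design text, 96 male SCID mice (a strain lacking functional B and T cells) were injected with the cells, and were assigned at random to 1 of 4 diets after 2 weeks of tumour growth. They were killed once the tumour volume exceeded 1000 mm3. The diets drew their fat from corn oil, fish oil, olive oil or a saturated fat source. Arrays of 6 tumours per diet were used, 24 in all, taken from the animals of median survival in each diet group. Tumours were frozen at once after excision, total RNA was extracted with Trizol, and the RNA was labelled with biotin, per the labels' protocols. Each array was treated as 1 tumour from 1 animal, as the design text describes.

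The deposited values were log2 probe set summaries made by the authors with RMA, per the submitters' processing notes. The software, its version and the chip definition are not given in the sources used here. The values ran from 2.49 to 14.32 with 2 decimals, and 0 cells were missing. The median log2 value per array lay between 5.84 and 5.97. By diet (mean ± SD, n = 6) it was 5.93 ± 0.035 on fish oil, 5.918 ± 0.025 on corn oil, 5.89 ± 0.033 on saturated fat and 5.865 ± 0.023 on olive oil. The interquartile range per array lay between 2.60 and 3.48, so the value distributions of the arrays were not identical. Correlations between arrays ran from 0.943 to 0.993 over 276 pairs, and 0 pairs were identical. The number of arrays limits the precision of every comparison.

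Of 22277 probe sets, 62 were control probe sets. In the platform annotation, 19064 of the other 22215 named exactly 1 gene, 1043 named several genes and 2108 had no gene listed. The Entrez identifier of 19052 of the single-gene probe sets matched the human gene table of assembly GRCh38.p14, which was used for symbols and for the span of each gene. Among the probe sets of a gene, the one with the highest mean over the 24 arrays represented it, which gave 11963 genes, 4310 of them with more than 1 probe set. Probe sets naming several genes or none were left out, and no filter on signal was set. Mouse RNA from the host reaches these probes only by cross-hybridisation.

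Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), in 1 fit with 4 diet means, no covariate and 20 residual degrees of freedom. The comparisons were an F test over the 4 diets, fish oil against the mean of the other 3 diets as the main comparison, and the 6 pairs of diets. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 11963 genes, with a threshold of 0.05. Errors given with a log2 difference are standard errors of the fit (SE), and errors given with a level are standard deviations (SD) over the 6 arrays of a diet.

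The analysis also used 32 gene lists, with at least 5 measured genes each. The lists covered oxidative phosphorylation, the mitochondrial ribosome, the citric acid cycle, glycolysis and hypoxia, fatty acid synthesis, fatty acid oxidation, cholesterol, eicosanoids, insulin and IGF signalling, androgen response, cell cycle, interferon, NF-kappaB, unfolded protein response, NRF2 targets, cytosolic ribosomal proteins, proteasome, heat shock proteins, MYC targets, apoptosis regulators, p53 targets and immediate early genes. A further 10 lists held markers of luminal, basal and neuroendocrine epithelium, fibroblasts, smooth muscle, skeletal muscle, endothelium, myeloid cells, adipocytes and erythroid cells. Each list was tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 32 lists of a comparison. Camera with an estimated correlation, fry and a permutation test of the mean of the list per array were set beside it. The permutation test was two-sided, used 100000 resamples for 6 against 18 arrays, and was exact over 924 splits for 6 against 6. The mean of a list per array is the mean over its genes of the log2 value minus the mean of that gene over the 24 arrays.

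The lists, the fit and the rule for naming genes were fixed before the data were examined. The rule took, for fish oil against the other diets, up to 10 genes past the threshold per direction, or else the 5 genes of smallest p. It then took the 2 genes of smallest p in each of the lists of main interest and a fixed set of lipid, insulin signalling and prostate genes. For each pair of diets it took the 3 largest changes per direction among genes past the threshold, or else the 2 genes of smallest p. A Y-linked gene that the rule takes on the fish oil and olive oil pair is not reported here, as levels of sex-linked marker genes are left out of the text.

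The fits were tested on simulated data drawn from the real means and residual spreads of the 11963 genes, with independent noise for each gene. For fish oil against the other 3 diets, 62% of 100 genes changed by 0.5 on the log2 scale and 94% of 100 genes changed by 1 were recovered, with 7 calls among unchanged genes. For fish oil against olive oil the shares were 36% and 84%, with 6 such calls. Noise in the real genes is correlated, so these numbers of false calls need not hold for the real data. Random regroupings of the real arrays called as many as 1074 genes for the first comparison and 1166 for the second. With independent noise, camera called 0 lists when none was shifted and 1 when 1 list was shifted by -0.25.

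Alternatives set beforehand were every probe set as its own row, the mean of the probe sets of a gene, genes above the median expression only, arrays re-centred on their median, quantile normalization repeated, an intensity trend with a robust prior, array quality weights, a fit of the 12 arrays compared, the replicate number as a block, an RNA quality covariate, a test without moderation, each array left out in turn, camera with an estimated correlation, and fry. The RNA quality covariate was the mean log2 ratio of the 3 prime to the 5 prime control probe sets of ACTB and GAPDH. Chosen after seeing the data were fits without 4 arrays that stood apart on principal component 1, without 4 arrays of an interquartile range below 3, with the interquartile range as a covariate, and the permutation test of list means. Calculations outside R used Python with pandas 2.3.3 and figures used matplotlib 3.10.9.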

Results

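Gene expression was measured in LAPC-4 prostate cancer xenografts from mice fed 1 of 4 fat sources, with 6 tumours and 6 arrays per diet. The question posed by the title of the series is whether the type of dietary fat matters for the progression of these tumours. Values are RMA summaries on the log2 scale, so a difference of 1 is a factor of 2 in signal. Fish oil is the source of long-chain omega-3 fatty acids among the 4 fats, corn oil is rich in omega-6 fatty acids, and olive oil is rich in monounsaturated fatty acids. RNA quality, read from the 3 prime to 5 prime ratio of the control probe sets, was 1.47 ± 0.42 (SD, n = 6) on fish oil and 1.20 ± 0.39 (SD, n = 18) on the other diets, a difference within the spread (permutation test, p = 0.154).

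Across the 4 diets, the F test of limma called 0 of 11963 genes, with a smallest adjusted p of 0.0905. At an unadjusted p under 0.05 there were 1810 genes, where 598 would be reached by chance with independent genes. The test without moderation also called 0 genes. Array quality weights gave 94 genes, and leaving out Olive oil replicate 3, Saturated fat replicate 3 or Corn oil replicate 4 gave 82, 20 or 2 genes.

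In tumours of mice fed fish oil, the genes of mitochondrial energy metabolism lay lower than in tumours on the other 3 diets. Of 64 measured nuclear-encoded subunits of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, 62 were lower on fish oil, by a mean of -0.26 on the log2 scale (limma's camera, adjusted p = 8.30e-24; adjusted p = 0.400 with an estimated correlation). All 51 measured genes of the mitochondrial ribosome, which translates the mitochondrial genome, were lower as well, with a mean of -0.31 (camera adjusted p = 3.62e-19; adjusted p = 0.400 with an estimated correlation). The means of all 6 fish oil arrays lay below the mean of the other 18 arrays in both lists. By permutation of the list means per array, p was 0.0031 for oxidative phosphorylation and 0.0049 for the mitochondrial ribosome, each with an adjusted p of 0.0525 over the 32 lists, which missed the threshold. Without the 4 arrays of an interquartile range below 3, Fish oil 1 and Fish oil 3 among them, the means were -0.18 and -0.20 (exact permutation, p = 0.0559 and 0.0768). No single gene passed over all genes in limma (0 of 11963, smallest adjusted p 0.0526), while 34 of the 64 and 23 of the 51 genes passed downward when adjusted over the list alone.

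**Figure D1:**
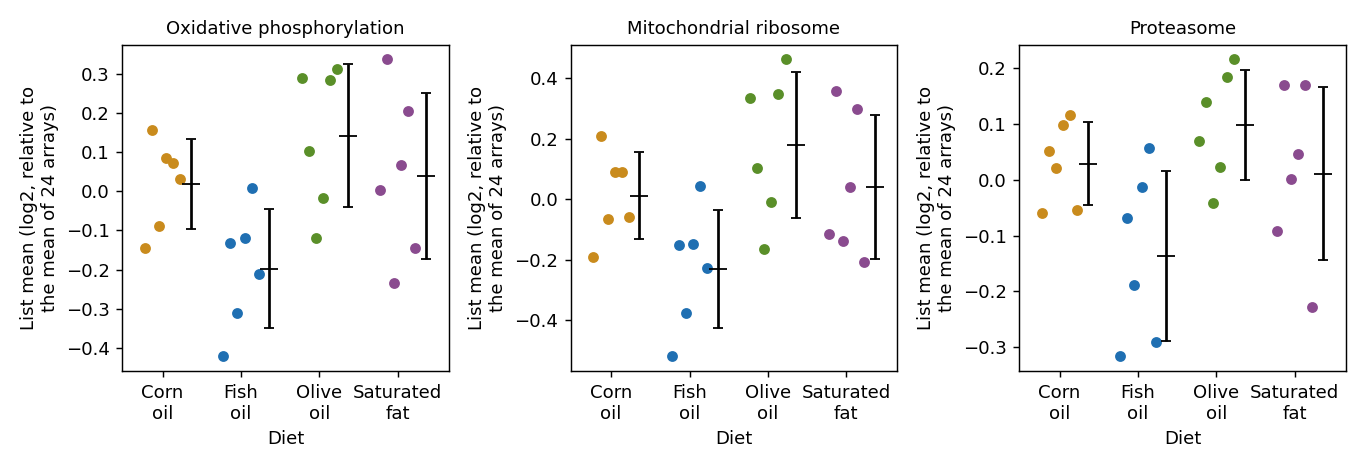
Mean of 3 gene lists per array (vertical axis, log2, relative to the mean of each gene over the 24 arrays) by diet (horizontal axis), with 1 point per tumour and the mean ± SD of 6 arrays in black. The fish oil tumours lie between -0.42 and 0.01 for oxidative phosphorylation, where the other 18 tumours lie between -0.23 and 0.34.

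The leading members of these lists were NDUFB2 and NDUFS4, subunits of respiratory complex I, and MRPS28 and MRPL13, proteins of the small and large mitochondrial ribosomal subunits. NDUFB2 had a log2 level of 10.07 ± 0.33 (SD, n = 6) on fish oil, and its log2 difference from the other diets was -0.56 ± 0.11 (SE; limma adjusted p = 0.0526). NDUFS4 differed by -0.81 ± 0.18 (adjusted p = 0.0544), MRPS28 by -0.71 ± 0.16 and MRPL13 by -0.84 ± 0.19 (adjusted p = 0.0584 for both). In the citric acid cycle list, 19 of 23 genes were lower, with a mean of -0.20 (camera adjusted p = 2.78e-05; 0.400 as the adjusted p with an estimated correlation), led by DLST at -0.31 ± 0.08 and SDHC at -0.41 ± 0.11. Its mean was -0.07 without the 4 arrays of an interquartile range below 3, and the call ended (adjusted p = 0.135). The members of these lists named here did not pass over all genes.

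Protein turnover and folding genes lay lower on fish oil in the same comparison. In the proteasome list, 27 of 32 genes were lower (mean -0.18, camera adjusted p = 1.36e-08), and in the heat shock protein list 17 of 20 were lower (mean -0.27, adjusted p = 1.69e-05; adjusted p = 0.400 for both with an estimated correlation). The proteasome mean was -0.09 with quantile normalization (adjusted p = 0.0134), and the median of the list lay at percentile 13.6 of random lists matched on gene span and expression, so it was not separated from them. Of 52 cytosolic ribosomal proteins, 45 were lower by a small mean of -0.09 (adjusted p = 8.66e-07; adjusted p = 0.400 with an estimated correlation), led by RPL10A at -0.50 ± 0.11 and RPL35A at -0.27 ± 0.07. With quantile normalization the mean was -0.05 (adjusted p = 0.0204). The cytosolic ribosomal list was not compared with matched random lists. Those matched to the oxidative phosphorylation list had a median of -0.09, so a general offset of short and abundant genes stays open here. Of 41 genes of glycolysis and the hypoxia response, 30 were lower (mean -0.17, adjusted p = 1.12e-04; adjusted p = 0.400 with an estimated correlation), and the glycolytic enzyme PGK1 and the mitophagy receptor BNIP3 were among the genes of smallest p in the whole comparison. The permutation p over arrays of these 4 lists was 0.0048, 0.0112, 0.0179 and 0.0315 in the order given, none under 0.05 after adjustment.

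Lists of sterol synthesis, androgen response and cell division were called downward as well. The cholesterol list was lower in 14 of 18 genes (mean -0.20, camera adjusted p = 0.0022; adjusted p = 0.400 with an estimated correlation), with IDI1 at -0.70 ± 0.18 and FDPS at -0.45 ± 0.13, both enzymes of isoprenoid synthesis. The androgen response list was lower in 37 of 47 genes (mean -0.20, adjusted p = 0.0011; adjusted p = 0.400 with an estimated correlation), with MED28 at -0.90 ± 0.23 and CENPN at -0.69 ± 0.20. The cell cycle list was lower in 43 of 68 genes (mean -0.09, adjusted p = 0.0070; adjusted p = 0.784 with an estimated correlation), with the mitotic genes CCNB2 at -0.54 ± 0.12 and MAD2L1 at -0.67 ± 0.19. The proliferation marker MKI67 was at 0.40 ± 0.20, in the other direction (limma adjusted p = 0.300). Its other probe sets gave 0.02, 0.32 and 0.18 (limma, unadjusted p = 0.925, 0.121 and 0.376). Without the 4 arrays that stood apart, the cholesterol list had an adjusted p of 0.0584 and the cell cycle list a mean of -0.0038 (adjusted p = 0.704), so neither was called. None of the 3 lists was called without the 4 arrays of an interquartile range below 3, and the cell cycle list changed sign (mean 0.03, adjusted p = 0.632). There the cholesterol list was at -0.14 (adjusted p = 0.102) and the androgen response list at -0.13 (adjusted p = 0.102). The cell cycle call also ended without Fish oil replicate 1 (mean -0.04, adjusted p = 0.176) or Fish oil replicate 3 (mean -0.01, adjusted p = 0.648). It ended with quantile normalization (adjusted p = 0.219), with array quality weights (adjusted p = 0.0566) and among genes above the median expression (adjusted p = 0.131), where the androgen call ended as well (adjusted p = 0.0681).

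The fatty acid oxidation list gave a mixed picture. It was called downward (mean -0.04, 31 of 47 genes lower, camera adjusted p = 0.0448; adjusted p = 0.400 with an estimated correlation), yet its genes of smallest p lay higher on fish oil. These were UCP2, an uncoupling protein of the inner mitochondrial membrane, at 0.77 ± 0.16, and ACOX3, a peroxisomal acyl-CoA oxidase, at 0.54 ± 0.11 (limma adjusted p = 0.0526 for both). Neither passed over all genes, and 2 genes passed upward and 2 downward when adjusted over the list alone. The list call ended without Corn oil replicate 2, Fish oil replicate 1, Fish oil replicate 3, Saturated fat replicate 2 or Saturated fat replicate 6. In that order the camera adjusted p was 0.0633, 0.176, 0.0656, 0.0509 and 0.0502, with means of -0.04, -0.02, -0.03, -0.04 and -0.04. The call ended as well without the 4 arrays that stood apart (mean -0.04, adjusted p = 0.137) and without the 4 of an interquartile range below 3 (mean -0.01, adjusted p = 0.377).

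Interferon response and NF-kappaB genes were called upward on fish oil. Of 47 interferon response genes 45 were higher, with a mean of 0.31 (camera adjusted p = 5.97e-04; adjusted p = 0.784 with an estimated correlation), led by MX2 at 0.61 ± 0.18 and CXCL10 at 0.40 ± 0.15. Of 35 NF-kappaB and cytokine genes 29 were higher, with a mean of 0.21 (camera adjusted p = 0.0415; adjusted p = 0.784 with an estimated correlation), led by CXCL6 at 0.16 ± 0.06 and CCL2 at 0.28 ± 0.11. These named genes were at low signal. On fish oil the mean log2 level was 3.26 for CXCL6, 3.80 for CCL2, 4.56 for CXCL10 and 5.25 for MX2. The fish oil arrays had medians of 5.89 to 5.97. The mean differences of both lists rested on Fish oil 1 and Fish oil 4, whose interferon list means were 0.92 and 1.19. The means of Corn oil 3 and Saturated fat 3 were 0.92 and 1.38, and the other 20 arrays lay between -0.44 and 0.22. Without these 4 arrays the mean difference was 0.05 for the interferon list and -0.0011 for the NF-kappaB list, and neither was called (adjusted p = 0.704 for both). Leaving out Fish oil replicate 1 or Fish oil replicate 4 alone also ended both calls. The means were then 0.17 and 0.12 for interferon (adjusted p = 0.160 and 0.331) and 0.09 and 0.08 for NF-kappaB (adjusted p = 0.705 and 0.429). The NF-kappaB call ended as well without Corn oil replicate 2, 4, 5 or 6 or Saturated fat replicate 1, 4 or 5, with an adjusted p from 0.0517 to 0.0704, though its mean stayed between 0.18 and 0.20. Interferon was at 0.19 (adjusted p = 0.102) and NF-kappaB at 0.09 (adjusted p = 0.792) without the 4 arrays of an interquartile range below 3. Among genes above the median expression they were at 0.27 (adjusted p = 0.121) and 0.02 (adjusted p = 0.769).

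**Figure D2:**
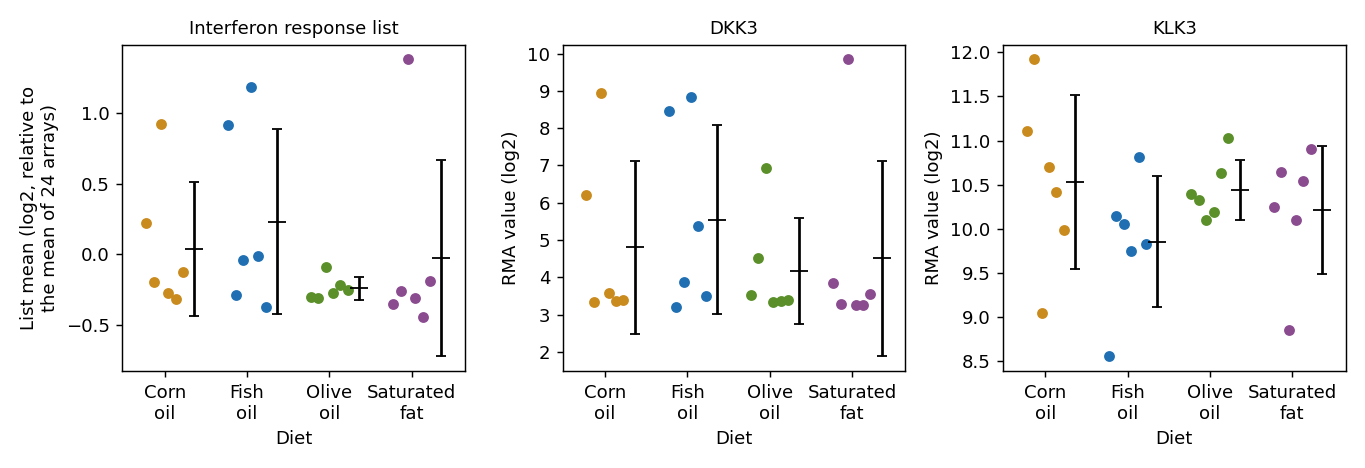
Interferon list mean per array (log2, relative to the mean of each gene over the 24 arrays) and RMA values (log2) of DKK3 and KLK3 by diet, with 1 point per tumour and the mean ± SD of 6 arrays in black. In Corn oil 3, Fish oil 1, Fish oil 4 and Saturated fat 3 the interferon list lies at 0.92 or above and DKK3 at 8.47 or above, while KLK3 lies at 9.75 or below.

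Among single genes in the same comparison, those of smallest p higher on fish oil were NOL6, a nucleolar protein of ribosome assembly, at 0.40 ± 0.07, and the tyrosine kinase FYN at 0.47 ± 0.09. Next came the lysosomal enzyme SGSH at 0.56 ± 0.11, OVGP1 at 0.47 ± 0.09 and HGH1 at 0.49 ± 0.10. Those lower were PGK1 at -0.54 ± 0.10, and the DNA repair factor XRCC4 at -0.64 ± 0.13, followed by BNIP3 at -0.62 ± 0.12, TMEM59 at -0.59 ± 0.12 and ETHE1, a mitochondrial sulfur dioxygenase, at -0.53 ± 0.11. All 10 had a limma adjusted p of 0.0526 and did not pass. Of the 3 other probe sets of XRCC4, 1 at low signal gave 0.02 and the others -0.32 and -0.40. At an unadjusted p under 0.05 there were 2038 genes, 1018 higher and 1020 lower. The test without moderation called 0 genes, and 379 genes had an adjusted p under 0.1. The count of 0 rose to 426 without Fish oil replicate 5, 265 without Olive oil replicate 3, 224 without Saturated fat replicate 3, 97 without Saturated fat replicate 1, 54 without Corn oil replicate 1 and 28 without Corn oil replicate 6. It was 269 with the arrays re-centred, 246 with the interquartile range as a covariate, 218 with the replicate number as a block, 201 with array quality weights, 159 among genes above the median expression and 74 with quantile normalization.

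None of the genes of insulin signalling and lipid metabolism fixed in advance passed the threshold. Over all 16 genes fixed in advance, KLK3, MKI67 and VEGFA among them, the log2 differences ran from -0.54 (KLK3) to 0.40 (MKI67). The smallest limma adjusted p was 0.300 (MKI67). IGF1R differed by -0.03 ± 0.12, INSR by 0.23 ± 0.14, IRS1 by 0.27 ± 0.20, IRS2 by 0.32 ± 0.48 and IGFBP3 by -0.18 ± 0.28. The lipogenic enzymes gave 0.15 ± 0.19 for FASN, 0.01 ± 0.12 for SCD and -0.04 ± 0.19 for FADS2, and other probe sets of FASN and SCD had the opposite sign. That of FASN gave -0.18 (limma, unadjusted p = 0.0797), and the 3 of SCD gave -0.14, -0.22 and -0.36 (unadjusted p = 0.293, 0.0437 and 0.0226). Targets of fatty acid sensing gave -0.05 ± 0.08 for PDK4, -0.01 ± 0.12 for CPT1A, -0.29 ± 0.14 for ANGPTL4 and -0.13 ± 0.09 for PLIN2. PTGS2, which makes prostaglandins, differed by 0.03 ± 0.23, VEGFA by -0.18 ± 0.17, and the androgen target KLK3 (prostate-specific antigen) by -0.54 ± 0.32. The KLK3 difference was -0.28 without Fish oil replicate 1, and its other probe set gave -0.87 (limma, unadjusted p = 0.0182). The 3 other probe sets of VEGFA gave -0.44, -0.24 and -0.10 (unadjusted p = 0.0324, 0.204 and 0.429), and the 2 of IGF1R gave 0.15 and 0.04, of the opposite sign. Leaving out single arrays moved IGFBP3 from -0.37 (Fish oil replicate 3) to -0.02 (Fish oil replicate 1), FASN from 0.09 (Fish oil replicate 2) to 0.25 (Fish oil replicate 1), VEGFA from -0.29 (Fish oil replicate 6) to -0.11 (Fish oil replicate 3) and PDK4 from -0.08 (Fish oil replicate 1) to -0.02 (Fish oil replicate 6). In the insulin and IGF list, 42 of 61 genes were higher with a mean of 0.11, which missed the threshold (camera adjusted p = 0.0515). Without the 4 arrays that stood apart it was called (mean 0.12, adjusted p = 0.0238), though not by exact permutation (unadjusted p = 0.0873). The means per diet were 0.08 on fish oil and 0.07 on corn oil, against -0.10 on olive oil and -0.05 on saturated fat. Fish oil and corn oil thus lay close, and the list was not called between them. Its genes of smallest p were EIF4E at -0.74 ± 0.16 and SHC1 at 0.47 ± 0.16.

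The remaining 19 lists, the insulin and IGF list among them, were not called, with means from -0.16 to 0.12 and camera adjusted p from 0.0504 to 0.937. Fatty acid synthesis had a mean of -0.02, led by ELOVL6 at -0.53 ± 0.21 and HACD3 at -0.46 ± 0.19, and eicosanoid metabolism a mean of -0.0036, led by PTGER4 at -0.77 ± 0.25 and PTGES3 at -0.26 ± 0.09. The NRF2 list had a mean of -0.09, with CBR1 at -0.57 ± 0.14 and NQO1 at -0.48 ± 0.14, and the unfolded protein list a mean of -0.05, with PDIA6 at -0.28 ± 0.07 and HYOU1 at 0.47 ± 0.15. MYC targets had a mean of -0.02, apoptosis regulators -0.02, p53 targets 0.06 and immediate early genes 0.03. Among marker lists the means were -0.16 for luminal and 0.10 for basal epithelium, 0.05 for neuroendocrine cells, 0.11 for fibroblasts, 0.10 for smooth muscle, 0.02 for skeletal muscle, 0.04 for endothelium, 0.06 for myeloid cells, -0.07 for adipocytes and 0.12 for erythroid cells. The median and mean differed in sign for eicosanoid metabolism, MYC targets and skeletal muscle.

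Fish oil against olive oil was the pair with genes past the threshold. Limma called 456 genes, 187 higher and 269 lower on fish oil, with log2 differences from -1.46 to 0.93, a median size of 0.60 and 30 genes of at least 2-fold. S100P, a calcium-binding protein, fell by 1.46 (SE 0.39, adjusted p = 0.0416), from 8.29 ± 0.75 (SD, n = 6) on olive oil to 6.84 ± 0.56 (SD, n = 6) on fish oil. MED28, a subunit of the Mediator complex of transcription, fell by 1.28 (SE 0.28, adjusted p = 0.0255). PLXNA1, a semaphorin receptor, rose by 0.93 ± 0.26 (SE, adjusted p = 0.0465), COPG2IT1 by 0.91 ± 0.22 (adjusted p = 0.0290) and UCP2 by 0.89 ± 0.20 (adjusted p = 0.0255).

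**Figure D3:**
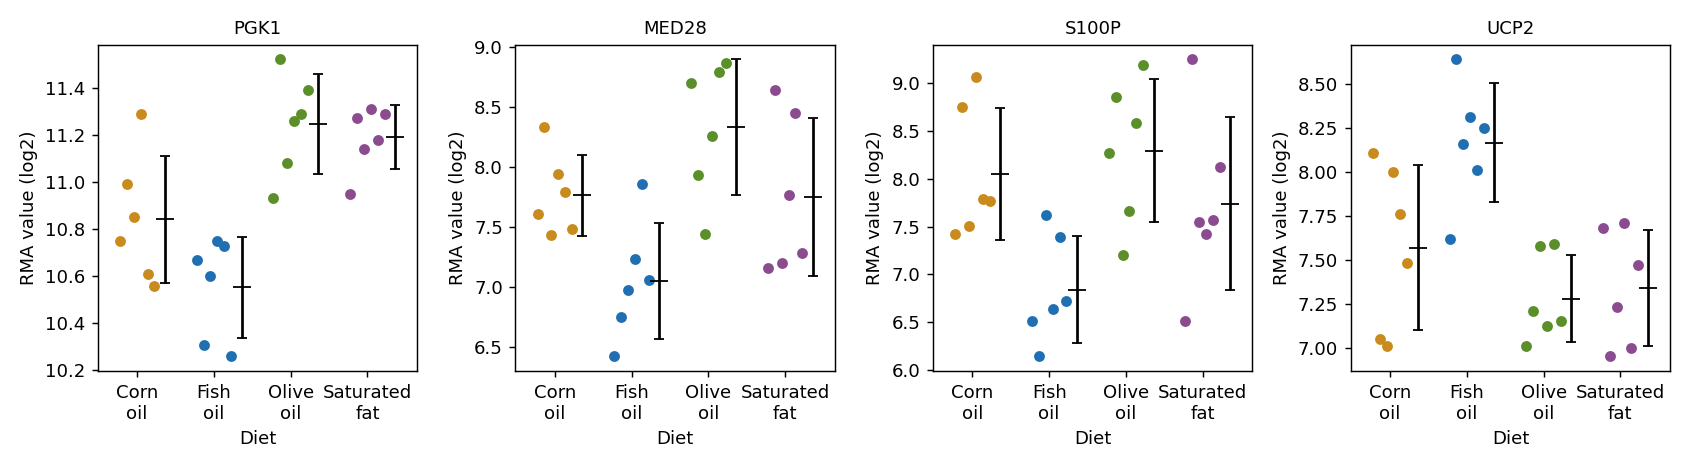
RMA values (vertical axis, log2) of PGK1, MED28, S100P and UCP2 by diet (horizontal axis), with 1 point per tumour and the mean ± SD of 6 arrays in black. PGK1 lies between 10.26 and 10.75 on fish oil and between 10.93 and 11.52 on olive oil, and UCP2 lies between 7.62 and 8.64 on fish oil and between 7.01 and 7.59 on olive oil.

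Mitochondrial genes fell in this pair in number. Among the 456 genes were 15 of the 64 oxidative phosphorylation genes and 9 of the 51 mitochondrial ribosome genes, all lower on fish oil (39 and 27 when adjusted over the list alone), with means of -0.34 and -0.41 for the lists. NDUFS4 fell by 1.05 and MRPL13 by 1.12 (limma adjusted p = 0.0255 for both). Also lower were 7 of 32 proteasome genes, 5 of 52 cytosolic ribosomal proteins, 4 of 23 citric acid cycle genes, 4 of 41 glycolysis and hypoxia genes including PGK1 and BNIP3, and 3 of 18 cholesterol genes. EIF4E, the cap-binding translation factor, fell by 1.08 and MAD2L1, a spindle checkpoint protein, by 1.07 (adjusted p = 0.0255 for both).

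Camera called 13 lists in this pair, 3 higher and 10 lower on fish oil. The lower lists included oxidative phosphorylation (adjusted p = 2.57e-21) and the mitochondrial ribosome (adjusted p = 1.07e-18), and the higher lists were interferon response (mean 0.47, adjusted p = 5.46e-04), NF-kappaB (mean 0.30, adjusted p = 0.0159) and insulin and IGF signalling (mean 0.18, 47 of 61 genes higher, adjusted p = 0.0088). With an estimated correlation the adjusted p was 0.519 or more for each list, and by exact permutation the smallest adjusted p was 0.0693. Without the 4 arrays that stood apart, Fish oil 1 and Fish oil 4 among them, interferon response had a mean of 0.06 and NF-kappaB of 0.0016 (adjusted p = 0.824 for both), so of the 3 higher lists insulin and IGF signalling was called (mean 0.18, adjusted p = 0.0075).

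The count of 456 depended on single arrays and on the other diets in the fit. It was 0 without Fish oil replicate 1, 2 or 6 or Olive oil replicate 5 or 6, 49 without Olive oil replicate 1, 119 without Fish oil replicate 3, 977 without Fish oil replicate 5 and 1091 without Olive oil replicate 3. A fit of the 12 arrays alone called 8 genes, the fit without the 4 arrays that stood apart called 0, and the test without moderation called 259. Re-centring the arrays on their medians changed the split to 98 higher and 705 lower. The array medians themselves ran from 5.89 to 5.97 on fish oil and from 5.84 to 5.90 on olive oil.

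Fish oil against corn oil gave 0 genes in limma (smallest adjusted p 0.639, 919 at an unadjusted p under 0.05, 0 without moderation). The mitochondrial lists lay lower on fish oil here too, with 62 of 64 oxidative phosphorylation genes (mean -0.22, camera adjusted p = 1.56e-17) and all 51 mitochondrial ribosome genes (mean -0.24, adjusted p = 4.90e-13). Camera called 16 lists, 4 higher and 12 lower, the higher ones being interferon response and the marker lists of myeloid cells, endothelium and fibroblasts. The smallest adjusted p was 0.350 with an estimated correlation and 0.231 by exact permutation. All 4 upward calls ended without the 4 arrays that stood apart, where interferon response was at -0.04, myeloid markers at 0.07, endothelium at 0.08 and fibroblasts at 0.03, and 11 lists were called downward. The genes of smallest p, none of which passed, were GLI1, a Hedgehog pathway transcription factor, at 0.39 ± 0.09 and FYN at 0.41 ± 0.11, and BACE2, an aspartyl protease, at -0.68 ± 0.15 and XRCC4 at -0.64 ± 0.15.

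Fish oil against saturated fat gave 0 genes in limma (smallest adjusted p 0.103, 1405 at an unadjusted p under 0.05, 0 without moderation). ACOX3 at 0.72 ± 0.14, BRD9 at 0.58 ± 0.11, PGK1 at -0.64 ± 0.12 and EIF4E at -0.90 ± 0.19 had the smallest p of their direction and did not pass. Of 64 oxidative phosphorylation genes 60 were lower on fish oil (mean -0.24, camera adjusted p = 2.27e-17), and 11 lists were called, 2 higher and 9 lower, against 7 lists without Fish oil replicate 1, Saturated fat replicate 4 or Saturated fat replicate 5. The smallest adjusted p was 0.818 with an estimated correlation and 0.502 by exact permutation. Of the 2 higher lists, interferon response was not called without the 4 arrays that stood apart (mean 0.13, adjusted p = 0.149), and insulin and IGF signalling was (mean 0.16, adjusted p = 0.0257).

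The pairs without fish oil gave 0 genes each in limma and 0 without moderation. Corn oil against saturated fat had 1244 genes at an unadjusted p under 0.05, with PDGFA, a platelet-derived growth factor, at 0.54 ± 0.12, TTC23 at 0.48 ± 0.11, CHRM2 at -0.37 ± 0.08 and DNAH9 at -0.43 ± 0.10 (adjusted p = 0.350 for each). In that pair 2 lists were called, the unfolded protein list upward (mean 0.13) and myeloid markers downward (mean -0.11), with an adjusted p of 0.999 for both with an estimated correlation. Corn oil against olive oil had 1381 such genes, with GOLGA1 at 0.53 ± 0.11, KCTD2 at 0.46 ± 0.10, TLR4, the receptor for bacterial lipopolysaccharide, at -0.43 ± 0.09 and the selenoprotein SELENOF at -0.83 ± 0.17 (adjusted p = 0.315 for each). Camera called 4 lists, with the mitochondrial ribosome (mean -0.17), oxidative phosphorylation (mean -0.12) and cytosolic ribosomal proteins (mean -0.08) lower and insulin and IGF signalling (mean 0.17) higher on corn oil, and an adjusted p of 0.998 for each with an estimated correlation. Olive oil against saturated fat had 160 such genes, with NAPG at 0.48 ± 0.15, CXCL14 at 0.31 ± 0.10, VASH1-AS1 at -0.36 ± 0.12 and WNT2B at -0.28 ± 0.10 (adjusted p = 0.995 for each). Camera called 10 lists there, 7 higher and 3 lower on olive oil, among them oxidative phosphorylation (mean 0.10) and the mitochondrial ribosome (mean 0.14), with an adjusted p of 0.747 for each with an estimated correlation. Without single arrays the 2 lists of corn oil against saturated fat became 4 (Corn oil replicate 2, 3 or 6), 1 (Corn oil replicate 4 or Saturated fat replicate 3) or 0 (Saturated fat replicate 6), and the 4 lists of corn oil against olive oil became 8 (Corn oil replicate 5). The 10 lists of olive oil against saturated fat became 6 (Olive oil replicate 2 or Saturated fat replicate 6) or 5 (Saturated fat replicate 3). In limma 1 gene passed between corn oil and saturated fat without Saturated fat replicate 6, and 1 between corn oil and olive oil without Olive oil replicate 3 or Saturated fat replicate 3.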

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

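All tests of explanations in this part were chosen after the results were seen, while the gap test was fixed beforehand. It asked whether the highest or lowest of the 6 arrays of a diet lay apart from the nearest other by a ratio of gap to range above Dixon's critical value at the 5% level. It was met in 19 of 296 groups of named genes (6.4%) and in 8 of 128 groups of list means (6.2%), where chance gives about 1 in 20.

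Among the list means, Saturated fat 3 was highest of its diet for the interferon response (1.38, nearest other -0.19, ratio 0.861) and fibroblast markers (0.62, nearest other 0.07, ratio 0.655). Corn oil 3 was highest for apoptosis regulators (0.29, nearest other 0.01, ratio 0.684), p53 targets (0.42, nearest other 0.04, ratio 0.649) and skeletal muscle markers (0.20, nearest other -0.05, ratio 0.7). Saturated fat 6 was highest for adipocyte markers (0.41, nearest other 0.07, ratio 0.633). Corn oil 6 was highest for erythroid markers (0.22, nearest other -0.02, ratio 0.683). Olive oil 6 was lowest for myeloid markers (-0.15, nearest other -0.03, ratio 0.631).

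Among the genes, Olive oil 3 gave 5 of the 19 values. It was lowest for BNIP3 (11.18, nearest other 11.47, ratio 0.707), CCNB2 (8.57, nearest other 8.97, ratio 0.8) and PTGER4 (8.14, nearest other 8.76, ratio 0.912). It was highest for COPG2IT1 (6.25, nearest other 5.46, ratio 0.693) and BRD9 (7.82, nearest other 7.47, ratio 0.66). Olive oil 5 was highest for CXCL10 (4.64, nearest other 4.17, ratio 0.691) and DNAH9 (5.62, nearest other 5.45, ratio 0.68) and lowest for TTC23 (5.44, nearest other 5.78, ratio 0.68). Olive oil 2 was highest for IRS2 (6.09, nearest other 5.21, ratio 0.786) and Olive oil 1 lowest for ANGPTL4 (8.56, nearest other 9.14, ratio 0.659). Saturated fat 3 was lowest for BNIP3 (10.69, nearest other 11.25, ratio 0.651) and highest for IRS2 (7.67, nearest other 5.25, ratio 0.896). Saturated fat 6 was highest for PDGFA (5.71, nearest other 5.24, ratio 0.644) and DNAH9 (5.94, nearest other 5.45, ratio 0.71). Fish oil 5 was lowest for HGH1 (7.82, nearest other 8.04, ratio 0.629) and PTGS2 (3.79, nearest other 4.78, ratio 0.811). Fish oil 1 was lowest for ELOVL6 (7.53, nearest other 8.32, ratio 0.767). Corn oil 6 was highest for CXCL10 (4.54, nearest other 4.10, ratio 0.772) and Corn oil 3 for CXCL14 (4.32, nearest other 4.05, ratio 0.643).

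Several of these arrays belong to a wider pattern. Corn oil 3, Fish oil 1, Fish oil 4 and Saturated fat 3 stood apart on principal component 1, which carried 32.6% of the variance. Genes picked after seeing the data show it: DKK3, a secreted Wnt regulator, lay at 8.93, 8.47, 8.84 and 9.84 in these arrays against 3.20 to 6.93 in the other 20. The basement membrane collagen COL4A1 lay at 10.08, 9.33, 9.59 and 10.09 against 4.27 to 7.23. CAV1 lay at 8.22, 8.10, 8.52 and 7.62 against 3.78 to 7.09. The luminal genes KLK3 (9.04, 8.55, 9.75 and 8.85 against 9.82 to 11.92) and EPCAM (10.64, 10.34, 10.60 and 10.45 against 10.69 to 11.58) lay below. The markers were graded, since Corn oil 1 (DKK3 6.21, COL4A1 7.23) and Olive oil 3 (DKK3 6.93, COL4A1 6.71) also lay above the medians of the other 20, 3.46 and 4.75. On principal component 1 the 4 arrays lay at 30.02 or above and the next, Fish oil 3, at 13.41.

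RNA quality or a narrow signal range is argued against as a trait shared by these 4 arrays. Of the 4, 3 lay inside the range of the other 20 in both the 3 prime to 5 prime ratio and the interquartile range. The remaining Corn oil 3 had the lowest ratio of all, 0.605. For Fish oil 1 a narrow signal range stays open, as its interquartile range was 2.77. Corn oil 3, Fish oil 4 and Saturated fat 3 lay at 3.30, 3.17 and 3.02 against a median of 3.205 in the other 20. Stroma of the mouse host stays open. The mean of COL1A1, COL1A2, COL3A1, DCN and LUM, abundant stromal genes, did not exceed the other 20 arrays in 4 of the 4 (7.66, 7.06, 8.23 and 8.11 against 6.98 to 8.32). Its members went opposite ways, so this mean does not decide: COL1A2 lay at 6.92, 6.66, 6.63 and 6.95 against a median of 6.00, and LUM at 7.50, 6.40, 9.55 and 9.29 against a median of 9.76. Another human cell population in the tumour, or a shift of the tumour cells away from the luminal state, may also explain the pattern, and these cannot be told apart here. The mean of the luminal list lay below each of the other 20 arrays in 3 of the 4 (-0.42, -0.46 and -0.46), but at -0.19 in Fish oil 4 it lay inside their range of -0.23 to 0.47. An effect of diet on the number of such tumours was not tested.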

How the results depend on the processing

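The fits without the 4 arrays that stood apart, without the 4 arrays of low signal spread, with the interquartile range as a covariate, and the permutation of list means were chosen after seeing the data. The other alternatives were planned.

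The oxidative phosphorylation and mitochondrial ribosome lists were lower on fish oil than on the other 3 diets under every alternative run, by -0.32 to -0.17 and by -0.36 to -0.20, with each array left out by -0.31 to -0.22 and by -0.36 to -0.25. They were called under each one that used camera at its preset correlation. With an estimated correlation 0 lists were called in each of the 7 comparisons, with the directional test of fry 0 in each, and by permutation of list means 0 in each. The mixed test of fry, which asks whether the genes of a list change in either direction, called 9 lists for fish oil against the other diets, 14 for fish oil against olive oil and 0 in the other comparisons. These tests, the mixed test included, allow for the correlation between the genes of a list. At its preset value camera takes this correlation as 0.01, while the estimate for oxidative phosphorylation was 0.542.

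Counts of genes were 0 for the F test and for fish oil against the other diets, and 456 for fish oil against olive oil. With array quality weights they were 94, 201 and 547, and 10 genes were called between corn oil and olive oil. With arrays re-centred they were 3, 269 and 803, with quantile normalization 4, 74 and 724 (and 1 for fish oil against saturated fat), and with the replicate number as a block 3, 218 and 665. With the RNA quality covariate they were 2, 0 and 673. Among genes above the median expression, where fewer genes were tested, they were 0, 159 and 762. With the interquartile range as a covariate they were 99, 246 and 1258, with 17 for fish oil against saturated fat, 5 for corn oil against olive oil and 1 for corn oil against saturated fat. Fish oil against olive oil gave 259 genes without moderation, 8 with only the 12 arrays compared, 0 without the 4 arrays that stood apart and 0 without the 4 of low signal spread. The fits with fewer arrays have fewer degrees of freedom. Corn oil against saturated fat gave 1 gene with every probe set as its own row and 1 without the 4 arrays of low signal spread. The cause of the other shifts was not tested.

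List counts from camera moved as well. Between fish oil and corn oil they fell from 16 to 8 among genes above the median expression, 9 with quantile normalization, 7 without the arrays of low signal spread and 9 with the interquartile range covariate. With fish oil against the other diets the count was 7 without the arrays of low signal spread, and for fish oil against saturated fat it was 6 there and 6 with quantile normalization. For corn oil against saturated fat it was 0 with quantile normalization, 0 with array weights, 0 without the arrays of low signal spread and 5 with the interquartile range covariate. For corn oil against olive oil it was 0 with array weights and 10 with the interquartile range covariate. For olive oil against saturated fat it was 5 among genes above the median expression, 2 with quantile normalization, 1 with array weights, 4 without the arrays of low signal spread and 6 with the interquartile range covariate. The cause was not tested.

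Some list means changed sign. Without the 4 arrays that stood apart, NF-kappaB was at -0.0011 for fish oil against the other diets and 0.0195 for olive oil against saturated fat. The interferon response was there at -0.0412 for fish oil against corn oil and 0.0677 for olive oil against saturated fat. The latter was called in the other direction (camera adjusted p = 0.0235). Without Saturated fat replicate 3 alone it was also at 0.0677, but not called (camera adjusted p = 0.173). The 4 arrays that stood apart carried the high values. Without the arrays of low signal spread, the cell cycle list was at 0.0288 for fish oil against the other diets and 0.0502 against corn oil. With array weights, NF-kappaB was at 0.0135 and the unfolded protein list at -0.0057 for olive oil against saturated fat. The cause of the last 4 was not tested.

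Genes fixed in advance that lay near 0 for fish oil against the other diets also changed sign. With the mean of the probe sets, IGF1R was at 0.0515, FASN at -0.0139 and SCD at -0.1763. With re-centring SCD was at -0.0433 and PTGS2 at -0.0211, and with quantile normalization FADS2 was at 0.0357, CPT1A at 0.0649 and PTGS2 at -0.0115. With array weights SCD was at -0.0682, PDK4 at 0.0036 and CPT1A at 0.0326, and with the RNA quality covariate IGF1R was at 0.0188, SCD at -0.0129 and PTGS2 at -0.0062. Without the 4 arrays that stood apart FADS2 was at 0.1543, CPT1A at 0.182 and PTGS2 at -0.0324. Without the arrays of low signal spread these were 0.0788, 0.1161 and -0.0154, and with the interquartile range covariate CPT1A was at 0.0164 and PTGS2 at -0.0179. None of these genes was called in the main comparison, and the cause was not tested.

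Leaving out each of the 24 arrays in turn gave 0 to 82 genes for the F test, 0 to 426 for fish oil against the other diets, 0 to 1091 for fish oil against olive oil, 0 to 1 for corn oil against olive oil and 0 to 1 for corn oil against saturated fat. List counts ran from 7 to 12 for fish oil against saturated fat, 0 to 4 for corn oil against saturated fat, 4 to 8 for corn oil against olive oil and 5 to 15 for olive oil against saturated fat. The interferon mean for olive oil against saturated fat ran from -0.2964 to 0.0677 and the NF-kappaB mean from -0.1893 to 0.0195. In the main comparison PTGS2 ran from -0.0374 to 0.2066, CPT1A from -0.0879 to 0.1201, IGF1R from -0.0953 to 0.0207, SCD from -0.0537 to 0.0783, FADS2 from -0.1406 to 0.1094 and IRS2 from -0.0293 to 0.5067.

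Over all alternatives and lists called at the outset, 2218 values kept direction and call, 446 kept direction without the call and 10 changed sign. Over named genes, 2450 values had the same direction and side of the threshold, 302 passed it where they had not, 70 no longer passed and 51 changed sign. Arrays give no depth per sample, so their number limits the precision.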

Other observations

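The tests without the 4 arrays that stood apart, and the tests of RNA quality and signal spread on the mitochondrial lists, were chosen after the data were seen, and the other tests in this part were written down before their results.

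Mitochondrial lists lay lower on fish oil than on each other diet. The difference was not carried by the 4 arrays alone, nor by a linear effect of the 3 prime to 5 prime ratio. The mean difference of the oxidative phosphorylation list was -0.25 without the 4 arrays against -0.26 over 24 arrays (exact permutation, unadjusted p = 0.0083, 4 against 16 arrays). It was -0.28 with the slope on that ratio taken out (permutation, unadjusted p = 0.0023). The ratio rests on ACTB and GAPDH, so other aspects of RNA quality stay open. Chance is not excluded either, as the permutation over 24 arrays gave an adjusted p of 0.0525 over the 32 lists. Against 10000 random lists matched on gene span and mean expression, the median of the list, -0.24, lay at percentile 0, below the lowest random median of -0.22. The genes of the random lists were drawn separately and lack the correlation between the genes of this list. The percentile thus bears on gene span and expression level, and does not weigh chance. Short and abundant genes in general did lie somewhat lower on fish oil, with a median of -0.09 in these matched lists against 0.02 over all genes, and the proteasome list at percentile 13.6 was not separated from its own matched lists. Signal spread stays open for part of the difference: without the 4 arrays of an interquartile range below 3, among them Fish oil 1 and Fish oil 3 with the lowest list means of their diet (-0.42 and -0.31), the oxidative phosphorylation difference was -0.18 (exact permutation, p = 0.0559), against -0.25 with the interquartile range as a covariate. Tumour growth and time of killing under each diet were not tested.

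The 456 genes between fish oil and olive oil had the same direction in all 456 cases without the 4 arrays that stood apart, where their median size was 0.58 against 0.60 over 24 arrays. No gene was called there, with a smallest limma adjusted p over all genes of 0.0586. The median SE of the 456 genes rose from 0.150 to 0.162, with 456 of the 456 still at an unadjusted p under 0.05. Over all genes, the number at an unadjusted p under 0.05 fell from 2645 to 2216. Why the calls ended was not tested. With the RNA quality covariate the median size was 0.59 and 402 of the 456 were called. The 456 genes were picked by their p in a fit of these same arrays, so their kept direction and size were favoured by the choice. Whether the 4 arrays were the cause is thus not decided. Over all genes, 0 were called without the 4 arrays and 673 with the RNA quality covariate. The count of 673 argues against RNA quality as the whole cause. Tumour growth, time of killing and the difference from the other pairs were not tested.

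Random regroupings of the arrays were run with 100 splits each, the real one included. Between fish oil and olive oil, 2 of 100 splits gave 456 genes or more (highest other split 1166), and 2 of 100 gave 2645 or more genes at an unadjusted p under 0.05 (highest other 3360). For this comparison taken alone, the share of splits lay under the level of 0.05. It rests on a sample of 99 other splits and was not corrected for the other comparisons, so chance is made less likely but is not excluded. The 456 also fell to 0 without any 1 of Fish oil replicate 1, 2 or 6 or Olive oil replicate 5 or 6. With fish oil against the other 3 diets, 6 of 100 splits gave 2038 or more genes at an unadjusted p under 0.05 (highest other 3300), so chance could not be excluded. For the counts of 0 the regroupings decide nothing, since each of 100 splits gives at least 0. The highest other counts were 262 for the F test, 1074 for fish oil against the other diets, 3117 for fish oil against saturated fat and 800 for olive oil against saturated fat. They were 0 for fish oil against corn oil, corn oil against saturated fat and corn oil against olive oil.

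List counts from camera with its preset correlation could not be told from chance in any comparison. As many lists as in the real split came from 30 of 100 splits for fish oil against the other diets (13 lists, highest other 24), 19 for fish oil against corn oil (16, highest other 22), 21 for fish oil against olive oil (13, highest other 19) and 51 for fish oil against saturated fat (11, highest other 22). The numbers were 98 for corn oil against saturated fat (2, highest other 22), 93 for corn oil against olive oil (4, highest other 18) and 49 for olive oil against saturated fat (10, highest other 24). A median of 10 lists was called over the 99 regroupings for fish oil against the other diets.

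Some regroupings called far more genes than the real split, up to 3117 between fish oil and saturated fat arrays and 1074 for fish oil against the rest, which points to a structure of the samples other than diet. The 1074 genes came from the only 1 of 99 other splits with all 4 of the arrays that stood apart on the fish oil side. The split of fish oil and olive oil arrays with 1166 genes had both such arrays on 1 side, as 47 of its 99 other splits did. These arrays do not account for all of it, however. Between fish oil and saturated fat arrays 8 of the 99 other splits called any gene, and 5 of these had the 3 such arrays on 1 side, as 21 of the 99 did. Splits of olive oil and saturated fat arrays, with 1 such array, reached 800 genes. What else the structure holds was not identified.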
